A study of Arabidopsis thaliana with 8 samples.

How the data were processed

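RNA was sequenced from whole seedlings of WT, agb1, hy5 and cry1 cry2 grown in blue light, with 2 libraries per genotype that the labels call biological replicates. The deposited tables give, per the file headers, raw read counts for each of 48321 transcript models, and the authors also gave RPKM, read counts scaled to model length and library total. In 1 table the RPKM column repeats the header of the reads column, and its unit was read from its values. Bowtie2 2.2.2 and the TAIR10 build are named in the submitters' processing notes. The counting tool, trimming, read length, strand and the handling of reads that match several places are not given in the sources used here. The lengths implied by the deposited RPKM of WT replicate 1 equal the annotated coding length less 2 or 3 bases in 99.95% of 28627 models compared. The RPKM was thus scaled to coding length, and whether the reads were counted over the same bases was not shown. RPKM was used for that check alone.

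Counts were summed over the transcript models of each locus, which gave 27628 loci, 10690 of them with more than 1 model. Whether a read in a stretch shared by several models was counted once per model is not given. The sums may therefore count reads more than once, which would make p values too small and Poisson intervals too narrow. Coordinates and product names came from the TAIR10.1 annotation, in which 27420 loci were matched by locus tag; it may differ from the build the authors used. Library totals ran from 15651218 to 23098347 counted reads. At the smallest total, 3 reads correspond to about 0.192 CPM. No 2 libraries were duplicates: between replicates the chi-square per degree of freedom was 2.34 to 3.44.

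Genes were tested with edgeR 4.0.16 in R 4.3.3 by quasi-likelihood F tests with TMM scaling (factors 0.931 to 1.12). Loci were kept by filterByExpr (minimum count 10, minimum total 15), which left 20695 of the 24741 loci with a read. All 8 libraries entered 1 fit with a mean per genotype, leaving 4 residual degrees of freedom; the common biological coefficient of variation was 0.0426. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, adjusted within each comparison. Standard errors were derived as the absolute log2 fold change divided by the square root of F. At an unadjusted p under 0.05, 5746 genes passed in agb1, 10237 in hy5 and 11626 in cry1 cry2. CPM values are scaled by the TMM factors and given as mean ± SD of 2 libraries. Intervals for near-absent transcripts are 95% Poisson intervals of the mutant reads.

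The comparisons were each mutant against WT, each pair of mutants against each other, and the overlap of calls for each pair. Overlaps were set against n1 × n2 / N per direction and against 50 simulated sets of unchanged groups compared with the same WT libraries. The 17 gene lists were fixed before the data were examined, with all of their 310 genes present in the tables: flavonoid synthesis, light-harvesting proteins with Rubisco small subunits, chlorophyll synthesis, light signalling, expansins with xyloglucan endotransglucosylase/hydrolases, auxin, gibberellin with brassinosteroid, clock, salicylate defence, jasmonate with ethylene defence, G protein components, cell division, nitrate with sulfate, heat, cold with drought and abscisic acid, root-enriched genes and seed genes. The last 2 mark other tissues. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 17 lists and 3 comparisons, and again with an estimated correlation. Camera compares a list with the other genes. Fry, used as an alternative, tests the members of a list against no change, so its results answer another question.

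Genes were named by a rule fixed before the data were examined: the 4 targeted genes; the 6 largest increases and decreases among called genes with a mean of at least 5 CPM and both mutant libraries beyond both WT libraries; up to 2 members of each list with the lowest p; and up to 3 genes per direction for each pair of mutants. RHD2, COBL9 and the neighbours of CRY2, as well as genes printed for a comparison other than the one that named them, were chosen after their values were seen.

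The procedure was tested on simulated data with 50 changed genes per fold. At 1.5-fold, 68%, 74% and 76% of these were recovered in the agb1, hy5 and cry1 cry2 designs, and at 2-fold 90%, 90% and 88%. In these designs 196, 185 and 188 genes were called, and 17, 8 and 9 of these were among the 20495 genes simulated as unchanged, counted before the filter. Only 200 genes were changed per design. The simulation therefore does not test scaling or error control at the shares of genes called in the data.

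Alternatives were median-ratio (RLE) scaling, library sizes alone, DESeq2 1.42.0, no filter on low counts, at least 5 CPM in 2 libraries, fits of the 2 compared genotypes alone, a replicate block, each library left out in turn, a 2-fold threshold, organelle genes left out, and fry or an estimated correlation for lists. The transcript model with most reads per locus was added after seeing the data. Pairing of equal replicate numbers was not established: correlations of same-number deviations between genotypes ran from -0.039 to 0.060, so no pairing term was used. With library sizes alone the median log2 fold change moved to 0.18 in cry1 cry2, -0.25 between agb1 and cry1 cry2 and -0.18 between hy5 and cry1 cry2. Tables and figures used Python 3.11.15 with pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Raw reads were not analysed here.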

Results

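Transcript levels were measured by RNA sequencing in whole seedlings of Arabidopsis thaliana, ecotype Col-0, grown under blue light. The seedlings were wild type (WT), the agb1 mutant (allele agb1-2), a hy5 mutant and the cry1 cry2 double mutant, with 2 biological replicates of each and 1 library per replicate, 8 libraries in all. AGB1 is the beta subunit of the heterotrimeric G protein. HY5 is a basic leucine zipper transcription factor that promotes light-dependent seedling development. CRY1 and CRY2 are cryptochromes, 1 class of blue-light receptors among several in the seedling. Seeds were kept in the cold (4 degrees) for 3 days, exposed to white light for 12 h and then held in blue light for 4.5 days on medium with 1% sucrose. The tables held between 15651218 and 23098347 reads per library, and 20695 of the 27628 loci had enough reads to be tested. A count by the transcript model with most reads per locus was the 1 alternative chosen after the result was seen. Within a genotype, log2 levels of the 2 libraries correlated across genes with r between 0.9957 and 0.9965. Genes within a library are not independent replicates, and these values describe only the closeness of the libraries.

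The targeted genes were examined first. CRY2 (AT1G04400, chromosome 1, bases 1185512 to 1188696 of TAIR10.1) had 3 and 4 reads in the cry1 cry2 libraries against 5006 and 4256 reads in WT, which is 0.0889% of the WT level (95% Poisson interval 0.0357% to 0.183%, counting error in the mutant only). CRY1 (AT4G08920, chromosome 4, bases 5723651 to 5727268) kept reads in cry1 cry2 but at a lower level, 80.2 ± 3.11 against 200.1 ± 3.48 normalised read counts scaled to library size (CPM; mean ± SD, n = 2; log2 fold change -1.32 ± 0.06 SE, adjusted p = 2.51e-18). AGB1 (AT4G34460, chromosome 4, bases 16477031 to 16479620) fell from 69.7 ± 7.68 CPM in WT to 43.8 ± 0.811 CPM in agb1 (log2 fold change -0.67 ± 0.07, adjusted p = 2.73e-08), and it was higher in hy5, at 86.0 ± 0.629 CPM (log2 fold change 0.30 ± 0.07, adjusted p = 4.37e-04). HY5 (AT5G11260, chromosome 5, bases 3593335 to 3595073) had 14.5 ± 0.697 CPM in the libraries labelled hy5 and 15.4 ± 0.663 CPM in WT (log2 fold change -0.09 ± 0.10, adjusted p = 0.488). The hy5 allele is not given in the sources used here, and some alleles leave the transcript in place. The reads at HY5 therefore neither check nor contradict the label of these 2 libraries.

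**Figure D1:**
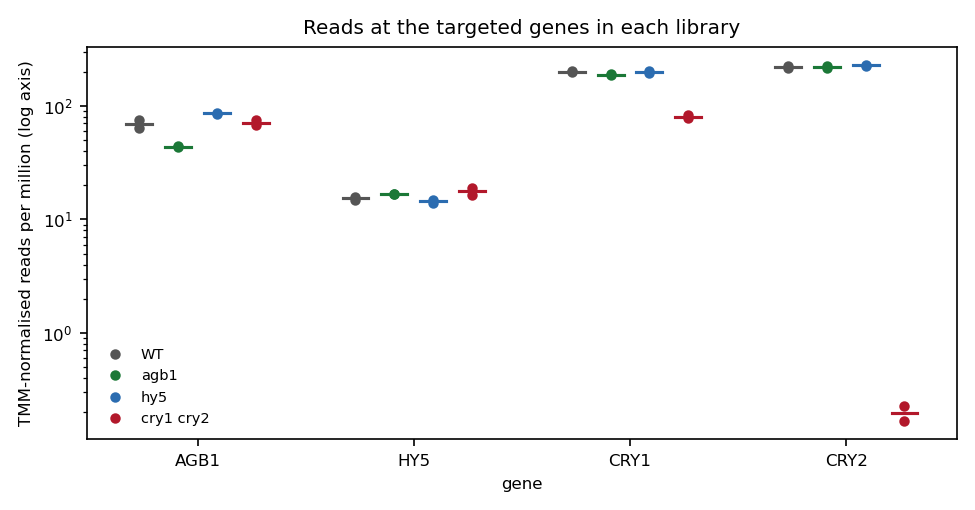
CPM (log axis) at AGB1, HY5, CRY1 and CRY2; each point is 1 library, colours mark the 4 genotypes and short bars the mean of the 2 libraries. CRY2 stands near 0.196 CPM in cry1 cry2 and above 200 CPM in the other genotypes, CRY1 and AGB1 are lowered in their own mutants, and HY5 lies between 14.0 and 18.9 CPM in every library.

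The comparison of agb1 with WT addresses which genes depend on the G protein beta subunit in blue light. Many genes of the photosynthetic apparatus and cold-responsive genes rose in agb1. Among auxin-response, cell-division and cell-wall-loosening genes more members fell than rose, although many were not called. With an estimated correlation no list call in agb1 passed the threshold. LHCB1.3, a major light-harvesting chlorophyll-binding protein, rose from 21045 ± 1210.0 to 32712 ± 169 CPM (log2 fold change 0.64 ± 0.05 SE, n = 2 per genotype), and chalcone synthase (CHS), the first enzyme of flavonoid synthesis, rose from 6.32 ± 0.547 to 27.7 ± 1.33 CPM (2.13 ± 0.11). The sulfate transporter SULTR1;2 fell from 96.8 ± 0.616 to 47.3 ± 0.373 CPM (-1.03 ± 0.06). In total 3553 genes changed, 1813 higher and 1740 lower, and 393 of them by at least 2-fold (212 higher, 181 lower).

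Among the fixed gene lists, that of light-harvesting proteins and Rubisco small subunits moved up: 17 of 24 tested members rose and 0 fell (18 changed when adjusted over the list alone). Light-harvesting and Rubisco genes had a median log2 fold change of 0.29 (camera adjusted p = 1.06e-13, and adjusted p = 0.175 with an estimated correlation). RBCS1A, a Rubisco small subunit, was among them (0.57 ± 0.05). In the chlorophyll biosynthesis list, 8 of 15 tested members rose and 0 fell (9 changed when adjusted over the list alone), PORB by 0.52 ± 0.05 and CHLG by 0.33 ± 0.06. With library sizes alone 4 members of that list rose and 0 fell. Chlorophyll genes had a median log2 fold change of 0.19 (camera adjusted p = 0.00229, and adjusted p = 0.187 with an estimated correlation). In the cold, drought and abscisic acid list, 8 of 10 tested members rose and 1 fell (9 changed when adjusted over the list alone), including the cold regulator CBF2 (1.56 ± 0.10) and RD29A (0.78 ± 0.05). Cold and drought genes had a median log2 fold change of 0.69 (camera adjusted p = 8.09e-13, and adjusted p = 0.0620 with an estimated correlation). In the salicylate and pattern-triggered defence list, 4 of 12 tested members rose and 1 fell (6 changed when adjusted over the list alone), with WRKY40 at 1.93 ± 0.13 and SID2, a salicylate biosynthesis enzyme, at 0.78 ± 0.09. Salicylate defence genes had a median log2 fold change of 0.18 (camera adjusted p = 0.00348, and adjusted p = 0.109 with an estimated correlation). In the flavonoid list, 4 of 18 tested members rose and 3 fell (8 changed when adjusted over the list alone); CHS and the flavonol synthase FLS1 (1.16 ± 0.21) rose. Flavonoid genes had a median log2 fold change of 0.22 (camera adjusted p = 0.0393, and adjusted p = 0.187 with an estimated correlation). The preset call of the flavonoid list was lost without WT replicate 2 (adjusted p = 0.107) and without agb1 replicate 2 (adjusted p = 0.0827). It was also lost with DESeq2 (adjusted p = 0.291), with no filter on low counts (adjusted p = 0.188), with at least 5 CPM in 2 libraries (adjusted p = 0.0662) and without organelle genes (adjusted p = 0.0715).

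Other lists moved down in agb1, growth-related ones among them. In the auxin response list, 2 of 29 tested members rose and 11 fell (18 changed when adjusted over the list alone); the auxin repressor IAA3 stood at -0.65 ± 0.07 and the auxin-conjugating enzyme GH3.3 at 1.27 ± 0.10. Auxin response genes had a median log2 fold change of -0.29 (camera adjusted p = 0.0106, and adjusted p = 0.187 with an estimated correlation). Among expansins and xyloglucan endotransglucosylase/hydrolases, which loosen cell walls, 4 of 25 tested members rose and 10 fell (15 changed when adjusted over the list alone), with XTH18 at -0.74 ± 0.06 and XTH9, in the opposite direction, at 0.97 ± 0.07. Wall-loosening genes had a median log2 fold change of -0.17 (camera adjusted p = 0.03997, and adjusted p = 0.442 with an estimated correlation). Without WT replicate 1 the preset call of that list was lost (adjusted p = 0.13), as it was without agb1 replicate 2 (adjusted p = 0.159) and with at least 5 CPM in 2 libraries (adjusted p = 0.0662). In the cell division list, 0 of 16 tested members rose and 5 fell (8 changed when adjusted over the list alone), among them the mitotic kinase CDKB2;1 (-0.52 ± 0.09) and the cytokinesis syntaxin KNOLLE (-0.45 ± 0.08). Cell division genes had a median log2 fold change of -0.40 (camera adjusted p = 0.0106, and adjusted p = 0.201 with an estimated correlation). In the list of light signalling components, 1 of 32 tested members rose and 9 fell (10 changed when adjusted over the list alone), with BBX25 at -0.48 ± 0.08 and BBX28 at -0.42 ± 0.06. Light signalling genes had a median log2 fold change of -0.10 (camera adjusted p = 0.0118, and adjusted p = 0.163 with an estimated correlation). In the nitrate and sulfate list, 1 of 8 tested members rose and 4 fell (5 changed when adjusted over the list alone), with SULTR1;2 and the sulfate-reducing enzyme APR3 (-0.39 ± 0.07) lower. Nitrate and sulfate genes had a median log2 fold change of -0.13 (camera adjusted p = 0.00494, and adjusted p = 0.187 with an estimated correlation).

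Markers of other tissues also moved in agb1. Among root-enriched genes, 2 of 16 tested members rose and 6 fell (9 changed when adjusted over the list alone), with the endodermal gene CASP1 at -0.80 ± 0.07 and PYK10, a root beta-glucosidase, at -0.54 ± 0.04. Root-enriched genes had a median log2 fold change of -0.24 (camera adjusted p = 1.80e-04, and adjusted p = 0.191 with an estimated correlation). Among seed storage and embryo genes, 1 of 14 tested members rose and 3 fell (6 changed when adjusted over the list alone); cruciferin CRA1 fell from 4.11 ± 0.761 to 1.03 ± 0.0986 CPM and the embryo regulator ABI3 rose from 1.73 ± 0.275 to 6.08 ± 0.534 CPM. The seed list had a median log2 fold change of -1.65, or -0.92 with the 3 members that had no reads in agb1 held at the bound set by 3 reads over the group, with a preset adjusted p = 0.0395 and adjusted p = 0.413 with an estimated correlation. Its preset call was lost without WT replicate 2 (adjusted p = 0.113), without agb1 replicate 1 (adjusted p = 0.0891) and without agb1 replicate 2 (adjusted p = 0.0606). The same call was lost with library sizes alone (adjusted p = 0.168), with only the 2 genotypes compared (adjusted p = 0.202), with at least 5 CPM in 2 libraries (adjusted p = 0.107) and with the transcript model that had most reads (adjusted p = 0.0896). Fry, which tests against no change and not against other genes, did not call the seed list (adjusted p = 0.106). For 5 lists camera made no call in agb1: gibberellin and brassinosteroid (2 members higher, 6 lower, adjusted p = 0.178), circadian clock (5 higher, 4 lower, adjusted p = 0.734), jasmonate and ethylene defence (2 higher, 3 lower, adjusted p = 0.300), heterotrimeric G protein components (1 higher, 1 lower, adjusted p = 0.734) and heat stress (0 higher, 0 lower by edgeR, 0 at an unadjusted p under 0.05, adjusted p = 0.734). Of the G protein components, the gamma subunit gene AGG3 stood at 0.76 ± 0.26 and the regulator RGS1 at -0.40 ± 0.11. The call of AGG3 was lost when any 1 of the WT or agb1 libraries was left out (adjusted p from 0.0918 to 0.23), and that of RGS1 without WT replicate 1 (adjusted p = 0.0964) or without agb1 replicate 2 (adjusted p = 0.203). AGG3 also lost its call with DESeq2 (adjusted p = 0.220), library sizes alone (adjusted p = 0.0598) and the transcript model with most reads (adjusted p = 0.109), and RGS1 with DESeq2 (adjusted p = 0.0671). Of the lists without a call, fry called gibberellin and brassinosteroid (adjusted p = 0.00748) and jasmonate and ethylene defence (adjusted p = 0.0141), both down.

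Among genes with a mean of at least 5 CPM over the 2 genotypes, the largest increases in agb1 were those of RRTF1, a redox-responsive transcription factor (0.642 ± 0.0403 to 10.7 ± 1.06 CPM, log2 fold change 4.05 ± 0.23), of AT3G16670 (3.01 ± 0.14) and of AT3G05727 (2.92 ± 0.10). They were joined by 3 annotated loci on chromosome 4, AT4G22505 (3.09 ± 0.17), AT4G22495 (2.92 ± 0.17) and AT4G22485 (2.56 ± 0.11). The first 2 of these loci lie over the same bases on opposite strands, as do the third and AT4G22475. Whether reads were counted by strand is not given, so their single values are uncertain. The largest decreases were those of AT3G58550 (33.4 ± 0.201 to 4.37 ± 0.358 CPM, -2.92 ± 0.11), the cytokinin hydroxylase CYP735A2 (-2.84 ± 0.13), QQS (-2.83 ± 0.22), AT1G30760 (-2.65 ± 0.08), the caffeoyl transferase FACT (-2.47 ± 0.13) and AT2G18370 (-2.05 ± 0.14). Their adjusted p lay between 1.49e-20 and 3.77e-11 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). DESeq2 called 2124 genes in agb1 (1108 higher, 1016 lower). Without WT replicate 2, 2350 were called (1188 and 1162), and without agb1 replicate 1, 2417 (1283 and 1134). Library sizes alone, without a scaling factor, gave 1248 higher and 2723 lower, or 31.4% of the calls as higher instead of 51.0%.

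The comparison of hy5 with WT addresses which genes depend on HY5 in blue light. In hy5, genes for light-harvesting proteins and the circadian clock mostly fell, as did single flavonol synthesis genes, and most genes for cell-wall loosening and auxin response rose. With an estimated correlation no list call in hy5 passed the threshold. LHCB1.2 fell from 3624 ± 164 to 504 ± 15.1 CPM (log2 fold change -2.85 ± 0.06 SE, n = 2 per genotype), flavanone 3-hydroxylase (F3H) fell from 10.3 ± 0.300 to 1.17 ± 0.417 CPM (-3.10 ± 0.19), and the clock gene PRR7 fell from 243 ± 5.22 to 83.8 ± 1.37 CPM (-1.53 ± 0.06). XTH17, a wall-modifying enzyme, rose from 154 ± 7.20 to 411 ± 6.10 CPM (1.42 ± 0.05). In total 8872 genes changed, 4683 higher and 4189 lower, of which 640 were higher and 666 lower by at least 2-fold.

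Among light-harvesting proteins and Rubisco small subunits, 6 of 24 tested members rose and 17 fell (23 changed when adjusted over the list alone). Light-harvesting and Rubisco genes had a median log2 fold change of -1.49 (camera adjusted p = 2.24e-55, and adjusted p = 0.0743 with an estimated correlation). LHCB3 fell (-2.31 ± 0.05), while the 4 Rubisco small subunit genes were among those that rose, RBCS1A by 0.17 ± 0.05. In the chlorophyll list, 1 of 15 tested members rose and 6 fell (7 changed when adjusted over the list alone), with PORB at -1.004 ± 0.05 and the cyclase CRD1 at -0.78 ± 0.05. Chlorophyll genes had a median log2 fold change of -0.07 (camera adjusted p = 0.0182, and adjusted p = 0.302 with an estimated correlation). In the clock list, 4 of 18 tested members rose and 12 fell (16 changed when adjusted over the list alone), with PRR5 at -1.26 ± 0.06. Clock genes had a median log2 fold change of -0.51 (camera adjusted p = 2.83e-10, and adjusted p = 0.0952 with an estimated correlation). In the cold, drought and abscisic acid list, 2 of 10 tested members rose and 5 fell (7 changed when adjusted over the list alone), with RD29A at -0.68 ± 0.05 and KIN1 at -1.59 ± 0.09. Cold and drought genes had a median log2 fold change of -0.46 (camera adjusted p = 0.0249, and adjusted p = 0.187 with an estimated correlation).

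Among expansins and xyloglucan endotransglucosylase/hydrolases, 19 of 25 tested members rose and 3 fell (22 changed when adjusted over the list alone), XTH18 by 1.29 ± 0.05. Wall-loosening genes had a median log2 fold change of 0.71 (camera adjusted p = 5.26e-17, and adjusted p = 0.0952 with an estimated correlation). In the auxin response list, 21 of 29 tested members rose and 2 fell (23 changed when adjusted over the list alone), with IAA19 at 1.22 ± 0.07 and IAA17 at 0.73 ± 0.06. Auxin response genes had a median log2 fold change of 0.49 (camera adjusted p = 5.76e-06, and adjusted p = 0.109 with an estimated correlation). In the gibberellin and brassinosteroid list, 11 of 22 tested members rose and 3 fell (14 changed when adjusted over the list alone), with GASA6 at 0.77 ± 0.06 and BEE1 at 0.76 ± 0.08. Gibberellin and brassinosteroid genes had a median log2 fold change of 0.23 (camera adjusted p = 0.0249, and adjusted p = 0.167 with an estimated correlation). In the jasmonate and ethylene list, 6 of 9 tested members rose and 0 fell (6 changed when adjusted over the list alone), with the vegetative storage proteins VSP1 (1.401 ± 0.09) and VSP2 (2.31 ± 0.18). Jasmonate and ethylene genes had a median log2 fold change of 0.36 (camera adjusted p = 0.00267, and adjusted p = 0.109 with an estimated correlation).

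The other lists had no preset camera call in hy5, although single members changed. In the flavonoid list, 8 of 18 tested members rose and 5 fell (13 changed when adjusted over the list alone) (adjusted p = 0.141); its median was 0.15 while its mean was -0.41, since F3H, CHS (-1.69 ± 0.18), FLS1 (to 0.105 ± 0.0660 CPM) and the repressor MYBL2 (-1.16 ± 0.06) fell. In the light signalling list, 9 members rose and 8 fell (adjusted p = 0.922), with BBX25 at 1.203 ± 0.07 and BBX22 at -1.33 ± 0.07. The counts of higher and lower members were 2 and 1 for salicylate and pattern-triggered defence (adjusted p = 0.464; RBOHD 1.15 ± 0.07), 1 and 1 for G protein components (adjusted p = 0.946; NDL2 0.40 ± 0.09, GPA1 -0.25 ± 0.06) and 2 and 3 for cell division (adjusted p = 0.520; MCM2 -0.81 ± 0.13, MCM5 -0.61 ± 0.11). They were 2 and 1 for nitrate and sulfate (adjusted p = 0.728; NRT1.1 0.30 ± 0.05), 2 and 0 for heat stress (adjusted p = 0.440; HSP90.1 0.39 ± 0.09), and 3 and 1 for seed storage and embryo genes (adjusted p = 0.977; ABI3 1.64 ± 0.20). Among root-enriched genes, 4 of 16 tested members rose and 10 fell (15 changed when adjusted over the list alone) (adjusted p = 0.0572 and adjusted p = 0.439 with an estimated correlation), with CASP1 at 1.11 ± 0.06, CASP2 at 1.11 ± 0.07 and root-hair genes such as RHD2 and COBL9 lower. The root list passed the preset test without WT replicate 2 (adjusted p = 0.0111), without hy5 replicate 2 (adjusted p = 0.0323) and without either cry1 cry2 library (adjusted p = 0.0452 and 0.0444). It also passed with no filter on low counts (adjusted p = 0.0374), the replicate block (adjusted p = 0.0466) and the transcript model with most reads (adjusted p = 0.0323). Fry, which tests against no change and not against other genes, called the root list too (adjusted p = 0.0192). Further lists called by fry were flavonoid, down (adjusted p = 0.00452), and salicylate defence and heat stress, up (adjusted p = 4.74e-04 and 0.00269).

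Among genes with a mean of at least 5 CPM over the 2 genotypes, the largest increases in hy5 were those of MRD1 (1.34 ± 0.127 to 31.0 ± 0.558 CPM, 4.53 ± 0.15), AT3G02670 (4.39 ± 0.23), AT1G48100 (3.38 ± 0.19), AT3G28270 (3.00 ± 0.19), AT1G10640 (2.98 ± 0.18) and AT1G73120 (2.88 ± 0.07). The largest decreases were those of AT1G65570 (10.6 ± 0.0747 to 0.689 ± 0.187 CPM, -3.95 ± 0.21), F3H, LHCB1.2, BHLH101, a regulator of the iron deficiency response (-2.75 ± 0.18), QQS (-2.67 ± 0.20) and AT2G03510 (-2.57 ± 0.10). Their adjusted p lay between 3.81e-25 and 7.70e-12 (edgeR). DESeq2 called 3457 genes higher and 2778 lower in hy5. The 5 LHCB1 genes are close copies of one another, and how reads were divided among copies is not given in the sources used here, so the split between them is uncertain. The Rubisco small subunit genes may share reads in the same way, so their rises may not be separate changes.

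The comparison of cry1 cry2 with WT addresses which genes depend on the cryptochromes in blue light. Most light-harvesting, clock and chlorophyll-synthesis genes fell, and most cell-wall-loosening and auxin-response genes and the tested seed genes rose. With an estimated correlation no list call in cry1 cry2 passed the threshold. LHCB1.2 fell from 3624 ± 164 to 136 ± 8.88 CPM (log2 fold change -4.74 ± 0.06 SE, n = 2 per genotype) and the nitrate reductase NIA2 fell from 2099.5 ± 76.2 to 560.0 ± 10.08 CPM (-1.91 ± 0.06). PORA, the protochlorophyllide reductase abundant in dark-grown seedlings, rose from 1.26 ± 0.389 to 126 ± 6.36 CPM (6.65 ± 0.12), and GASA4, a gibberellin-regulated gene, rose from 215 ± 6.13 to 1004 ± 24.1 CPM (2.22 ± 0.05). In total 10634 genes changed, 5292 higher and 5342 lower, of which 963 were higher and 1476 lower by at least 2-fold.

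Among light-harvesting proteins and Rubisco small subunits, 1 of 24 tested members rose and 23 fell (24 changed when adjusted over the list alone), with LHCB1.1 at -4.06 ± 0.06 and RBCS1A at -1.80 ± 0.05. Light-harvesting and Rubisco genes had a median log2 fold change of -2.43 (camera adjusted p = 2.51e-106, and adjusted p = 0.0620 with an estimated correlation). The 5 LHCB1 loci together took 5.48% and 5.19% of all reads in WT, 7.31% and 7.15% in agb1, 1.61% and 1.64% in hy5 and 0.833% and 0.769% in cry1 cry2. In the chlorophyll list, 2 of 15 tested members rose and 12 fell (14 changed when adjusted over the list alone); CRD1 fell (-2.24 ± 0.05), and PORA and PORB (1.06 ± 0.05) were the members that rose. Chlorophyll genes had a median log2 fold change of -1.21 (camera adjusted p = 2.49e-06, and adjusted p = 0.109 with an estimated correlation). In the clock list, 2 of 18 tested members rose and 15 fell (17 changed when adjusted over the list alone), with PRR5 at -2.45 ± 0.07 and LNK2 at -2.56 ± 0.06. Clock genes had a median log2 fold change of -1.42 (camera adjusted p = 2.16e-17, and adjusted p = 0.0620 with an estimated correlation). In the light signalling list, 7 of 32 tested members rose and 21 fell (28 changed when adjusted over the list alone), with BBX25 at -2.34 ± 0.09 and BBX22 at -2.12 ± 0.08. Light signalling genes had a median log2 fold change of -0.57 (camera adjusted p = 3.75e-04, and adjusted p = 0.109 with an estimated correlation). In the flavonoid list, 6 of 18 tested members rose and 9 fell (15 changed when adjusted over the list alone), with MYBL2 at -3.35 ± 0.07 and PAL2 at -1.45 ± 0.06. Flavonoid genes had a median log2 fold change of -0.74 (camera adjusted p = 0.0296, and adjusted p = 0.201 with an estimated correlation). In the cold, drought and abscisic acid list, 2 of 10 tested members rose and 7 fell (9 changed when adjusted over the list alone), with KIN1 at -2.09 ± 0.10 and RD29A at -1.34 ± 0.05. Cold and drought genes had a median log2 fold change of -1.60 (camera adjusted p = 0.0249, and adjusted p = 0.187 with an estimated correlation). The preset call of the flavonoid list was lost with no filter on low counts (adjusted p = 0.466), and that of the cold list with at least 5 CPM in 2 libraries (adjusted p = 0.110).

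Among expansins and xyloglucan endotransglucosylase/hydrolases, 20 of 25 tested members rose and 3 fell (23 changed when adjusted over the list alone), with XTH17 at 1.99 ± 0.06 and XTH19 at 1.91 ± 0.06. Wall-loosening genes had a median log2 fold change of 0.85 (camera adjusted p = 7.59e-12, and adjusted p = 0.109 with an estimated correlation). In the auxin response list, 20 of 29 tested members rose and 4 fell (25 changed when adjusted over the list alone), with IAA19 at 2.29 ± 0.06 and IAA17 at 1.38 ± 0.06. Auxin response genes had a median log2 fold change of 0.41 (camera adjusted p = 7.99e-05, and adjusted p = 0.109 with an estimated correlation). In the gibberellin and brassinosteroid list, 14 of 22 tested members rose and 3 fell (18 changed when adjusted over the list alone), with the biosynthesis enzyme GA20ox1 at 2.75 ± 0.18. Gibberellin and brassinosteroid genes had a median log2 fold change of 0.51 (camera adjusted p = 1.70e-04, and adjusted p = 0.0952 with an estimated correlation). Among seed storage and embryo genes, 14 of 14 tested members rose and 0 fell (14 changed when adjusted over the list alone), with CRA1 rising to 32.0 ± 4.29 CPM (2.97 ± 0.13) and CRC to 18.9 ± 6.89 CPM (4.48 ± 0.27). Seed genes had a median log2 fold change of 2.98 (camera adjusted p = 5.76e-06, and adjusted p = 0.187 with an estimated correlation). Among root-enriched genes, 7 of 16 tested members rose and 0 fell (6 changed when adjusted over the list alone), CASP1 by 1.08 ± 0.06 and CASP2 by 1.17 ± 0.07. Root-enriched genes had a median log2 fold change of 0.14 (camera adjusted p = 0.0149, and adjusted p = 0.335 with an estimated correlation). The lists without a preset call were salicylate defence (2 members higher, 2 lower, adjusted p = 0.602; EDS1 0.32 ± 0.08), jasmonate and ethylene defence (7 and 2, adjusted p = 0.359; VSP2 2.42 ± 0.18, LOX2 -3.05 ± 0.19), G protein components (1 and 1, adjusted p = 0.995; NDL1 -0.82 ± 0.06), cell division (5 and 0, adjusted p = 0.257; CYCB1;4 0.66 ± 0.10). The others were nitrate and sulfate (3 and 3, adjusted p = 0.195; NIA1 -0.94 ± 0.05) and heat stress (5 and 0, adjusted p = 0.288; HSP90.1 0.43 ± 0.09). All 6 of these lists were called by fry, which tests against no change, in a comparison where 51.4% of all tested genes were called. It called salicylate defence, jasmonate and ethylene defence, cell division and heat stress up (adjusted p = 0.00246, 0.00269, 0.0135 and 5.61e-04). G protein components and nitrate and sulfate were called down (fry adjusted p = 0.0139 and 7.83e-04), although their median log2 fold changes were 0.026 and 0.015. With DESeq2 the nitrate and sulfate list also passed (adjusted p = 0.0404). The member counts depend on scaling. With library sizes alone the higher and lower members were 6 and 1 for G protein components and 11 and 0 for cell division. They were 4 and 0 for salicylate defence and 4 and 2 for nitrate and sulfate, and stayed at 7 and 2 for jasmonate and ethylene and 5 and 0 for heat stress.

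**Figure D2:**
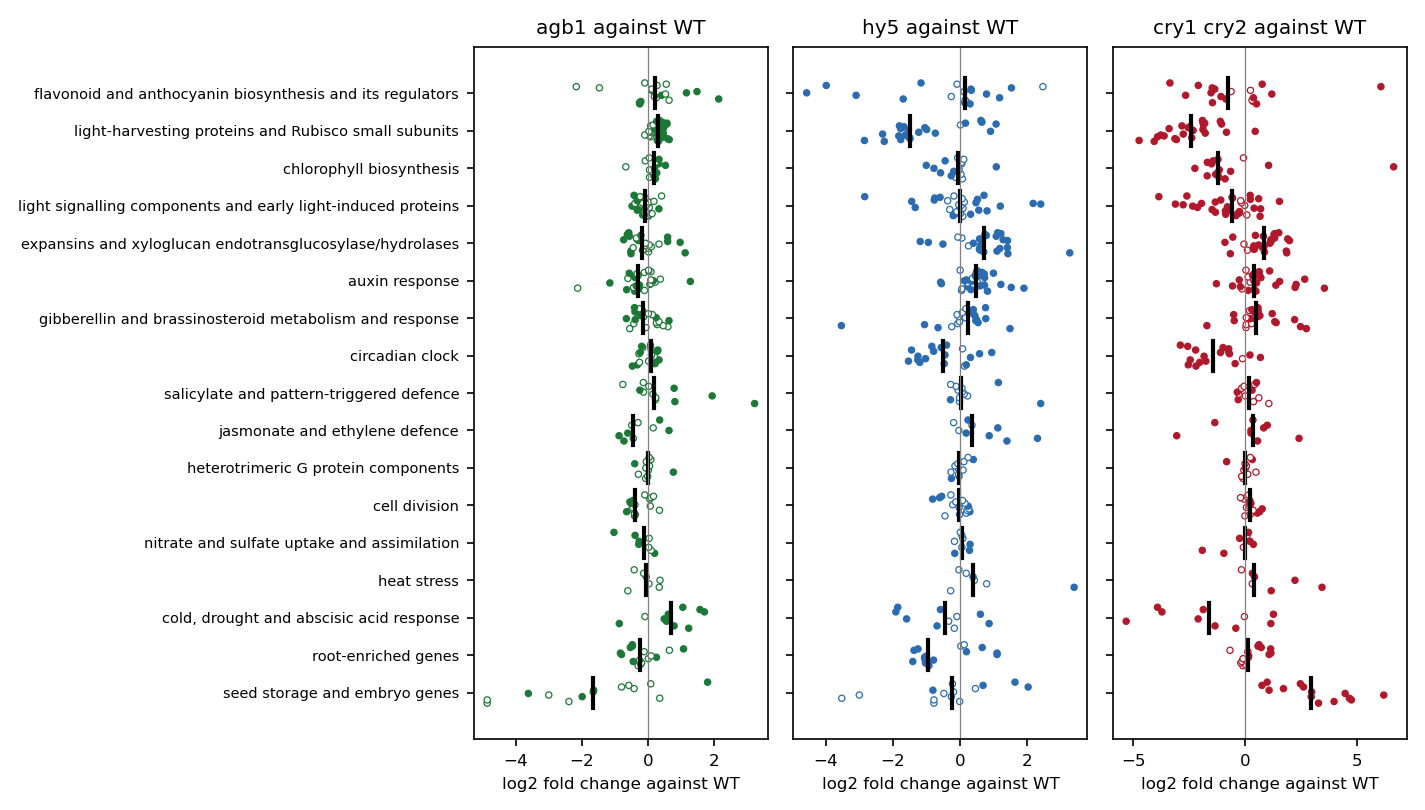
Log2 fold changes against WT (horizontal axis, one scale per panel) of the tested members of the 17 fixed gene lists in agb1, hy5 and cry1 cry2; each point is 1 gene, filled where its adjusted p is under 0.05, and the vertical bar is the list median. The light-harvesting list has medians of 0.29 in agb1, -1.49 in hy5 and -2.43 in cry1 cry2, and the auxin list medians of -0.29, 0.49 and 0.41. Members without reads in a group are drawn at their fitted value.

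Among genes with a mean of at least 5 CPM over the 2 genotypes, the largest increases in cry1 cry2 after PORA were those of GRF7, a growth-regulating factor (0.585 ± 0.258 to 36.4 ± 1.38 CPM, 5.97 ± 0.18), the wax ester synthase WSD1 (5.31 ± 0.29), the transcription factor HEC2 (5.29 ± 0.22), AT5G44440 (36.6 ± 1.15 to 898 ± 7.35 CPM, 4.62 ± 0.06) and AT2G47780 (4.57 ± 0.14). Several genes had almost no reads in cry1 cry2. The cytosolic malate dehydrogenase gene c-NAD-MDH1 (AT1G04410, chromosome 1, bases 1188995 to 1191458 of TAIR10.1) had 13 reads over both libraries against 826 ± 47.9 CPM in WT, or 0.0441% of the WT level (95% Poisson interval 0.0235% to 0.0754%). The next gene, AT1G04420, an annotated NAD(P)-linked oxidoreductase (bases 1191519 to 1193884), had 0 reads in both libraries against 44.2 ± 0.768 CPM in WT, which is at least 525-fold lower, taking 3 reads over the group as the floor. CIPK20, a calcium-sensor-interacting kinase, stood at 0.124% of WT (0.0337% to 0.316%) and the thionin THI2.2 at 0.291% (0.0794% to 0.746%). AT2G15020 had 1 read over both libraries, 0.125% of WT (0.0032% to 0.695%), as did COR15B, a cold-regulated gene, at 0.174% (0.0044% to 0.972%). Intervals and floors cover counting error only. The edgeR adjusted p of these genes lay between 1.40e-32 and 1.02e-19. Library sizes alone gave 8551 genes higher and 3542 lower, or 70.7% of the calls in cry1 cry2 as higher instead of 49.8%.

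**Figure D3:**
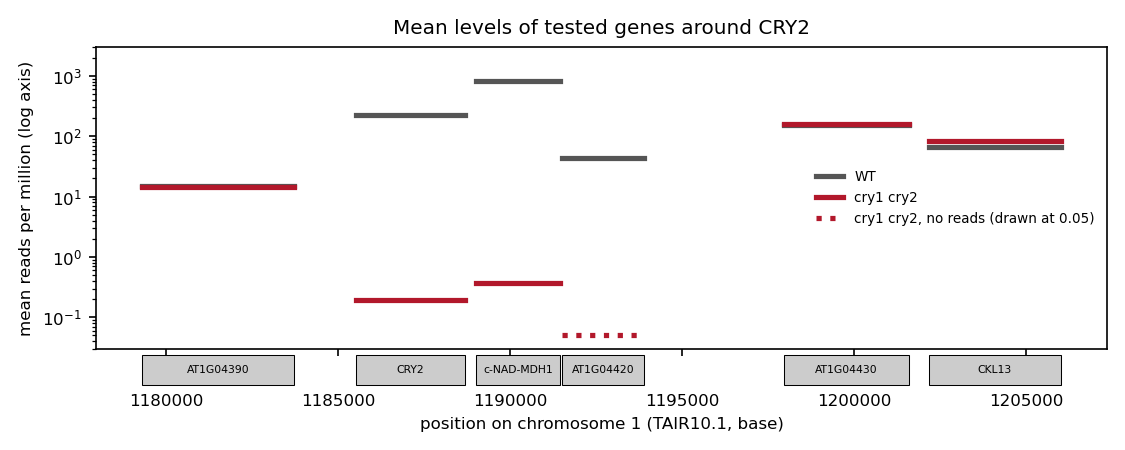
Mean CPM (log axis, n = 2 per genotype) of the tested genes around CRY2 on chromosome 1, drawn over their annotated extent in TAIR10.1 with WT in grey and cry1 cry2 in red. CRY2, c-NAD-MDH1 and AT1G04420, which lie side by side, drop to 0.196, 0.365 and 0 CPM in cry1 cry2, while AT1G04390 and AT1G04430 on either side stand at 14.6 and 160.2 CPM, against 14.9 and 153.9 CPM in WT.

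The mutants were then compared with each other, which bears on whether AGB1, HY5 and the cryptochromes affect the same genes. Calls against WT in agb1 and in either of the other mutants lay mostly in opposite directions, and calls in hy5 and cry1 cry2 mostly in the same direction. AT3G05730 rose from 105 ± 8.29 CPM in WT to 330.4 ± 7.15 CPM in agb1 and fell to 24.7 ± 5.33 CPM in hy5 and 24.1 ± 1.86 CPM in cry1 cry2. AT1G23130 had log2 fold changes of 1.47 ± 0.07, -1.56 ± 0.09 and -3.45 ± 0.12 in the same order, and AT1G30760 had -2.65 ± 0.08, 1.07 ± 0.06 and 0.84 ± 0.06. AT3G22125 rose in agb1 (1.63 ± 0.08) and fell in cry1 cry2 (-2.92 ± 0.13).

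Between agb1 and hy5, 2281 genes were called in both, 1564 in opposite and 717 in the same direction, where independent lists of these sizes would give 761 and 762. Between agb1 and cry1 cry2, 2677 genes were called in both, 2104 in opposite and 573 in the same direction, where independent lists would give 913 of each. Between hy5 and cry1 cry2, 6156 genes were called in both, 5229 in the same and 927 in opposite directions, where independent lists would give 2279 and 2280. These expected counts treat every tested gene as equally likely to be called. Genes with more reads may be called more readily in both mutants, which would raise the overlap in either direction. That was not tested. Examples of the same direction in agb1 and hy5 were AT1G29090 (1.65 ± 0.06 and 1.95 ± 0.06), GH9B15 (1.64 ± 0.07 and 1.62 ± 0.07) and CP1 (1.22 ± 0.06 and 1.45 ± 0.06). In agb1 and cry1 cry2, GRP9 (-0.99 ± 0.06 and -1.28 ± 0.06) and ORG1 (-0.77 ± 0.06 and -2.03 ± 0.06) fell together. In hy5 and cry1 cry2, THI2.2 (1.84 ± 0.07 in hy5), AT3G21670 (1.5 ± 0.06 and -2.01 ± 0.09) and XTH15 (-1.19 ± 0.05 and 1.17 ± 0.05) went opposite ways.

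**Figure D4:**
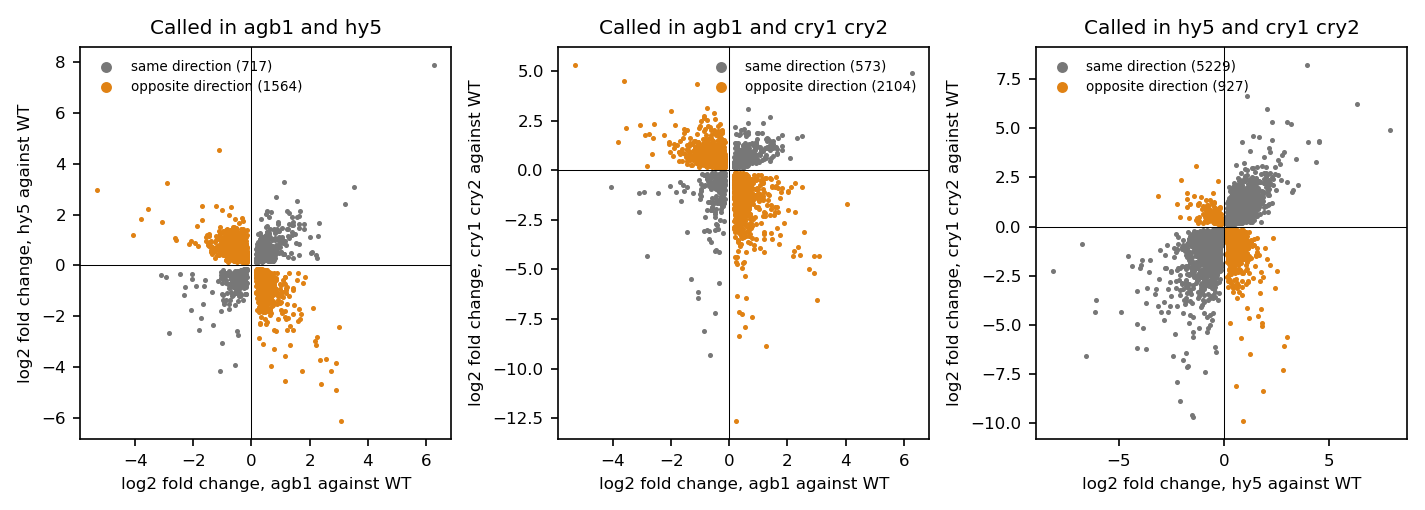
Log2 fold changes against WT of genes called in both mutants of a pair (axes as labelled); each point is 1 gene, grey where both changes have the same sign and orange where they differ. Genes of opposite sign number 1564, 2104 and 927 in the panels from left to right, and those of the same sign 717, 573 and 5229. Genes without reads in a group are drawn at their fitted value.

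These comparisons share the WT libraries, which alone makes fold changes correlate. In 50 simulated sets of unchanged groups against the same WT, the correlation across genes averaged 0.46 for agb1 with hy5, 0.46 for agb1 with cry1 cry2 and 0.47 for hy5 with cry1 cry2, and at most 2, 1 and 1 genes were called in both. The observed correlations were -0.08, -0.19 and 0.45. The observed covariances were -0.018, -0.063 and 0.209, against simulated means of 0.0194, 0.0194 and 0.0192. With 2 WT libraries the controls cannot be split into 2 sets of 2, so part of the overlap of hy5 and cry1 cry2 may come from the shared controls. Without WT replicate 1 the opposite calls numbered 925 for agb1 with hy5, 1310 for agb1 with cry1 cry2 and 596 for hy5 with cry1 cry2. Without WT replicate 2 the first 2 of these numbered 1041 and 1398. Same-direction calls for agb1 with hy5 numbered 418 without WT replicate 2, and those for agb1 with cry1 cry2 numbered 370 and 331 without WT replicates 1 and 2.

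Tested directly against each other, agb1 and hy5 differed in 10326 genes (5003 higher in agb1), agb1 and cry1 cry2 in 11985 (5953 higher in agb1) and hy5 and cry1 cry2 in 9046 (4792 higher in hy5). Differences of at least 2-fold numbered 2152, 3530 and 1957. For LHCB1.3 the direct difference was 2.40 between agb1 and hy5 and 1.3 between hy5 and cry1 cry2, with adjusted p of 3.27e-25 and 6.50e-20. RBCS1A differed by 1.96 between hy5 and cry1 cry2 (adjusted p = 5.87e-24) and CBF2 by 2.15 between agb1 and hy5 (adjusted p = 1.29e-15). With library sizes alone, the share of differences higher in the first genotype was 38.4% instead of 48.5% for agb1 and hy5, 27.5% instead of 49.7% for agb1 and cry1 cry2, and 28.2% instead of 53.0% for hy5 and cry1 cry2.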

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

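The transcript model with most reads per locus was the 1 setting chosen after the result was seen. It called 2942, 7712 and 9534 genes in agb1, hy5 and cry1 cry2, against 3553, 8872 and 10634 with summed counts. Of the 3553 calls in agb1 it kept 2850. No list or gene called against WT passed the threshold in the other direction under another setting. Between mutants, 2 of the 11985 genes that differed between agb1 and cry1 cry2 did so with library sizes alone. Of the values for named genes, 2909 kept their direction and side of the threshold, 13 lost the call, 4 gained one and 10 changed sign without a call in either setting. Of those for lists, 881 kept both, 50 lost the call, 20 gained one and 18 changed sign without a call in either setting. Both tallies include fits without a library of a genotype outside the comparison, where the compared libraries stay the same and little can change. With library sizes alone the majority direction of calls turned in some comparisons: the higher share went from 51.0% to 31.4% in agb1, from 49.8% to 70.7% in cry1 cry2 and from 53.0% to 28.2% between hy5 and cry1 cry2. Of the counts, 434 stayed within 1.5 times and 55 moved further. For the counts below, the cause was not tested, except that a 2-fold threshold adds a condition and leaving out a library leaves fewer samples. DESeq2 called 2124 genes in agb1, and its overlaps (same, opposite) were 369 and 981 for agb1 with hy5, 305 and 1322 for agb1 with cry1 cry2, and 578 opposite for hy5 with cry1 cry2. At least 2-fold left 393, 1306 and 2439 genes against WT, 2152, 3530 and 1957 between mutants, and overlaps of 44 and 68, 44 and 102, and 546 and 63. Leaving out 1 library gave 2350 to 3682 genes in agb1, 6772 to 8981 in hy5, 8996 to 10738 in cry1 cry2, 8440 to 10447, 10239 to 12109 and 7485 to 9058 between mutants, same-direction overlaps of 418 to 748, 331 to 587 and 4031 to 5202, opposite ones of 925 to 1605, 1310 to 2166 and 596 to 923, and 9 to 12, 8 to 9 and 11 to 11 called lists; the lone library left in a genotype is assumed to vary like the others. With an estimated correlation 0, 0 and 0 lists were called (camera, with 3, 5 and 7 at an unadjusted p under 0.05). Fry, which tests against no change and not against other genes, called 17 in cry1 cry2. With the replicate block 3476, 8751 and 10549 genes were called, no named gene crossed the threshold and the root list in hy5 did (adjusted p = 0.0466). Depth limits statements on transcripts under about 0.192 CPM.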

Other observations

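The gene lists in this paragraph and the next, and the list of loci on chromosome 4 further down, were chosen after the result was seen, so their p values describe them and are no independent evidence. Rapidly induced stress regulators, which answer wounding, cold and touch within minutes, rose together in agb1: 13 of 13 tested members rose and 0 fell in agb1, with a median log2 fold change of 1.61 (camera adjusted p = 2.83e-59 with the preset correlation and 0.00768 with an estimated correlation). ZAT12 stood at 1.59 ± 0.11 and ERF6 at 1.61 ± 0.11. A difference in handling or harvest between the genotypes was not tested and could not be told apart from genotype here. This limit holds for every change in agb1, hy5 and cry1 cry2, also those of RRTF1, CBF2 and WRKY40 in agb1 above. Of the same list, 2 of 13 tested members rose and 0 fell in hy5 (adjusted p = 0.579 with the preset correlation and 0.760 with an estimated correlation), and 0 of 13 tested members rose and 6 fell in cry1 cry2 (adjusted p = 0.346 with the preset correlation and 0.639 with an estimated correlation). Glucosinolate synthesis genes, which make sulfur-containing defence compounds, also rose in agb1: 11 of 15 tested members rose and 0 fell in agb1 (adjusted p = 5.66e-09 with the preset correlation and 0.0161 with an estimated correlation), BCAT4 by 1.205 ± 0.36; 6 of 15 tested members rose and 2 fell in hy5 and 8 of 15 tested members rose and 5 fell in cry1 cry2 (preset adjusted p = 0.466 and 0.228).

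Iron deficiency genes were lower in hy5: 0 of 12 tested members rose and 12 fell in hy5 (camera adjusted p = 4.31e-17 with the preset correlation and 0.0177 with an estimated correlation), with the regulator BHLH38 at -3.91 ± 0.29 and the peptide gene IMA1 at -2.81 ± 0.36. In the other mutants 0 of 12 tested members rose and 6 fell in agb1 (adjusted p = 1.00e-04 with the preset correlation and 0.0912 with an estimated correlation) and 0 of 12 tested members rose and 11 fell in cry1 cry2 (adjusted p = 3.21e-06 with the preset correlation and 0.0638 with an estimated correlation). Nuclear genes for photosystem subunits followed the light-harvesting genes: 21 of 23 tested members rose and 0 fell in agb1 (adjusted p = 7.67e-15 with the preset correlation and 0.0817 with an estimated correlation), 0 of 23 tested members rose and 20 fell in hy5 (adjusted p = 1.05e-29 with the preset correlation and 0.0381 with an estimated correlation) and 0 of 23 tested members rose and 22 fell in cry1 cry2 (adjusted p = 2.95e-90 with the preset correlation and 0.0105 with an estimated correlation). Of the plastid-encoded genes, 3 of 88 tested members rose and 0 fell in agb1 (adjusted p = 0.00975 with the preset correlation and 0.687 with an estimated correlation), 9 of 88 tested members rose and 43 fell in hy5 (adjusted p = 1.31e-04 with the preset correlation and 0.619 with an estimated correlation) and 3 of 88 tested members rose and 64 fell in cry1 cry2 (adjusted p = 2.11e-04 with the preset correlation and 0.619 with an estimated correlation). Aquaporin genes, for water channels, went the other way: 0 of 18 tested members rose and 12 fell in agb1 (adjusted p = 2.06e-06 with the preset correlation and 0.194 with an estimated correlation), 15 of 18 tested members rose and 1 fell in hy5 (adjusted p = 3.16e-11 with the preset correlation and 0.0912 with an estimated correlation) and 14 of 18 tested members rose and 0 fell in cry1 cry2 (adjusted p = 3.21e-06 with the preset correlation and 0.194 with an estimated correlation).

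The tests of shared WT libraries, of a root share, of the loci on chromosome 4 and of a deletion were chosen only after the result was seen, as were the G-box comparisons beyond the first. Genes called in agb1 and in hy5 or cry1 cry2 mostly moved in opposite directions. Shared WT libraries would push the covariance of fold changes above 0, and it was -0.063 for agb1 with cry1 cry2. Scaling of libraries with different light-harvesting shares is argued against as the whole cause by an opposite share under 3 other scalings of at least 78.52% with cry1 cry2, and of at least 68.3% with hy5. A root share that differs in hy5 would, as the only cause, move root-enriched genes 1 way, and 4 rose while 10 fell. The list median in hy5 was -0.94, so a root share acting beside other changes is not excluded there. In cry1 cry2 a different share of root in the seedlings stays open, since 0 fell and 7 rose while 6 of 8 called ones fell in agb1. Of the seed list, which also marks other tissue, 14 of 14 tested members rose in cry1 cry2. In agb1 1 of its members rose and 3 fell, and in hy5 3 rose and 1 fell. A difference in seed tissue or stage between the seedlings was not tested and stays open too. That AGB1 opposes HY5 and cryptochrome effects remains an untested hypothesis here.

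A run of 13 annotated loci on chromosome 4, AT4G22460 to AT4G22520 (bases 11838960 to 11858970), moved mainly up in agb1 (9 rose, 2 fell) and down in hy5 (2 rose, 10 fell), and both ways in cry1 cry2 (5 rose, 8 fell; camera adjusted p = 0.398 with the preset correlation and 0.543 with an estimated correlation). Reads shared between near-identical copies are argued against as the cause, since the median member had 0% of its 50-base coding stretches at a locus elsewhere; shorter or inexact matches were not tested. Reads counted at loci annotated over the same bases may make 1 change appear at several loci: 11 of the 13 overlap another member, and the median member had 83.4% of these stretches at a locus that overlaps it. The 2 that overlap no other member went opposite ways in cry1 cry2: in agb1, hy5 and cry1 cry2, AT4G22490 (179 reads in WT) had log2 fold changes of 1.83, -0.47 and 1.195, and AT4G22520 (26 reads in WT) had 2.27, -2.82 and -2.09. The number of separate genes that changed stays open.

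The loss of reads at CRY2 and its 2 neighbours is consistent with a deletion across adjacent loci in the cry1 cry2 line: among 15 loci at 1% or less of WT there was 1 run of 3 or more, and it holds CRY2. The loci on either side had log2 fold changes of -0.04 and 0.06 (adjusted p = 0.789 and 0.381). No locus fell to that level in agb1 or hy5 among those with at least 5 CPM in WT. Genomic reads were not available, so the extent of a deletion was not measured, and a loss of transcription across the 3 genes was not tested. Effects of cry1 cry2 may in part come from the loss of c-NAD-MDH1 and AT1G04420.

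A hypothesis was tested that genes lower in hy5 and higher in agb1 carry the G-box CACGTG, which HY5 binds, more often within 500 bases upstream than genes lower in hy5 and not called in agb1. It was present in 12.9% of 692 against 8.91% of 3186 (odds ratio 1.508, 95% interval 1.17 to 1.94, Fisher exact p = 0.00216, adjusted over 5 tests 0.00539). Genes lower in both mutants had it in 12.0% of 267 (odds ratio 1.08 for the first set against these, 0.704 to 1.67, Fisher exact p = 0.746), so the excess was not shown to be specific to opposite directions. Genes lower in hy5 had it about as often as genes not called there (9.77% against 9.98%, odds ratio 0.977, Fisher exact p = 0.717). Genes higher in hy5 had it more often (11.6%, odds ratio 1.19, Fisher exact p = 0.00202). So did all genes higher in agb1 (12.2%, against 9.99% of genes not called there, odds ratio 1.253, Fisher exact p = 0.0037). The first comparison came out as the hypothesis predicts, but its excess may go with a rise in agb1 whatever the change in hy5. It therefore cannot be assigned to HY5, and a role of HY5 binding stays open.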
